A study of Mus musculus with 16 samples.

How the data were processed

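Total RNA from fetal liver cell suspensions of mouse embryos was labelled with biotin using an Affymetrix whole-transcript kit and hybridised to 16 arrays, 1 female and 1 male sample in each of 8 groups (4 genotypes at 2 stages), per the labels' protocols. Embryos were genotyped by PCR before the livers were taken, per the labels. The deposited values are log2 signal per probe set made by the authors with RMA (background correction, normalization and summary), per the submitters' processing notes, which give no version; the values are rounded to 2 decimals. Scanner files were not used here, so background correction could not be varied.

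The value table held 28270 probe sets, of which 21780 were paired with 1 gene symbol, 1617 with several and 4873 with none. Each symbol was represented by its probe set with the highest mean over all arrays. Probe sets above the 30th percentile of all values (3.74) on at least 2 arrays were kept, which left 16258 test units, 15742 with 1 symbol and 516 with several; genes named in the text have 1 symbol. Symbols were checked against a table of gene identifiers for 21689 probe sets. No genome build is given for the probe sets, so no positions are printed.

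All 16 arrays were fitted in R 4.3.3 with limma 3.58.1, using 1 mean per stage and genotype group and labelled sex as a covariate (7 residual degrees of freedom). All groups shared 1 estimate of the spread. Comparisons of genotypes over both stages average the stage-specific differences, 4 arrays against 4. Tests were two-sided, with eBayes and Benjamini-Hochberg adjustment over the test units at a threshold of 0.05. A sex by GATA1s term was added for the comparisons of GATA1s carriers by sex (6 residual degrees of freedom). Stage by genotype terms were tested with 1 F test per gene.

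Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 18 lists of a comparison, with an estimated correlation and with fry. No list in any comparison passed with an estimated correlation; the smallest adjusted p, 0.0864, was in ERG/GATA1s against ERG. The lists were erythroid; embryonic and adult globins; megakaryocyte and platelet; stem cell transcription factors; stem and progenitor; GATA1-repressed; fetal programme and IGF; granulocyte and monocyte; mast cell, basophil and eosinophil; macrophage; hepatoblast and hepatocyte; endothelial; stellate and mesenchymal; lymphoid; cell cycle; interferon response; p53 response; and stress and immediate early genes. Shared calls were tested with Fisher's exact test over genes.

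The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule takes the 10 largest rises and falls past the threshold per comparison (5 for a single stage, and the 5 smallest p where fewer than 5 pass), Erg, Gata1, Gata2 and sex markers, and up to 4 members of each list whose shift passed. The fits were tested on simulated data: for ERG against WT over both stages they recovered 95% of genes changed 2-fold and 62% of those changed 1.5-fold.

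Alternatives were no filter or a stricter filter on dim probe sets, a further quantile normalization, centring each array on its median, no sex term, only the arrays compared, arrayWeights, the sex by GATA1s term in every comparison, eBayes with trend and robust, all probe sets, and leaving out each array in turn. Leaving out the 3 arrays whose sex markers oppose their label, and a Y-linked level as covariate in place of labelled sex, were chosen after seeing the data.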

Results

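Fetal liver is the main site of blood formation in the mouse embryo at midgestation, and the 16 arrays measured messenger RNA in single-cell suspensions of it. The embryos were wild type (WT), carried an ERG transgene (ERG), carried the GATA1s knock-in allele (GATA1s), or carried both (ERG/GATA1s). Whether females carried 1 copy of that X-linked allele or 2 is not given in the sources used here. GATA1 is the transcription factor that directs red cell and megakaryocyte development, and GATA1s is its short isoform, which lacks the start of the protein. ERG is a transcription factor of blood stem cells and megakaryocytes. Each of the 8 groups, 4 genotypes at E12.5 and at E14.5, held 1 array labelled female and 1 labelled male. The labels do not say whether a sample was 1 embryo or a pool, so p-values measure the spread between these samples. The deposited log2 signal ran from 1.96 to 13.32 over 28270 probe sets, with array medians from 4.79 to 4.94. The number of arrays limits the precision: the median residual SD, after group means and labelled sex were fitted, was 0.1615 on the log2 scale.

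The levels of Erg and Gata1, the genes of the design, came first. Erg signal was 5.51 and 5.35 in the E12.5 WT arrays labelled female and male, 5.58 and 5.63 in ERG, 5.69 and 5.80 in GATA1s, and 6.01 and 5.90 in ERG/GATA1s. At E14.5 it was 5.41 and 5.53 in WT, 5.88 and 5.58 in ERG, 5.32 and 5.55 in GATA1s, and 5.80 and 5.66 in ERG/GATA1s. Erg was 0.22 ± 0.10 (SE) higher in ERG than in WT over both stages, in 4 of 4 pairs of arrays of the same stage and labelled sex, and did not pass limma's test (adjusted p = 0.655). In ERG/GATA1s it rose by 0.39 ± 0.10 (adjusted p = 0.0252, 4 of 4 pairs), a call lost without the E12.5 WT array labelled male, the E14.5 WT array labelled female or either E14.5 ERG/GATA1s array, where its adjusted p reached 0.118. The transgene's species and sequence are not given in the sources used here, so whether the mouse probe set measures it is not known. Gata1 signal in the same order was 9.76, 10.02, 9.69, 9.36, 9.56, 9.58, 9.60 and 9.30 at E12.5. At E14.5 it was 9.22, 9.22, 9.22, 9.29, 9.26, 9.64, 9.53 and 9.40. Probe sequences are not held, so whether the Gata1 probe set tells the isoforms apart was not checked, and neither gene was used to check a label.

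Xist, which is transcribed from the inactive X chromosome of females, and the Y-linked genes Eif2s3y, Kdm5d and Uty were set against the labelled sex. The E14.5 ERG/GATA1s array labelled female had an Xist signal of 4.22 and a mean Y-linked signal of 6.50, both on the side of the arrays labelled male. The E12.5 GATA1s array labelled male (Xist 9.83, Y-linked 3.77) and the E12.5 ERG/GATA1s array labelled male (9.51 and 3.92) lay among the arrays labelled female. Xist and Y-linked signal were both present in the E12.5 WT array labelled male (9.35 and 4.947) and the E14.5 ERG array labelled male (10.03 and 5.273). The E12.5 ERG array labelled male lay between the clusters (5.73 and 5.61). Ddx3y was not among the named probe sets and has no value. Every direction by sex below is therefore one between arrays labelled male and arrays labelled female. By markers, both E14.5 ERG/GATA1s arrays lay with those labelled male. Both E12.5 GATA1s and both E12.5 ERG/GATA1s arrays lay with those labelled female. Labelled sex as a covariate cannot remove such differences. Effects of these groups, against other genotypes or between stages, can therefore include an effect of sex or of copies of the X-linked allele. Without the 3 arrays whose markers oppose their label, a choice made after seeing the data, the calls over both stages fell from 46 to 5 for ERG against WT, from 620 to 141 for GATA1s and from 1720 to 241 for ERG/GATA1s. Those for effects that differ between stages fell from 393 to 6.

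**Figure D1:**
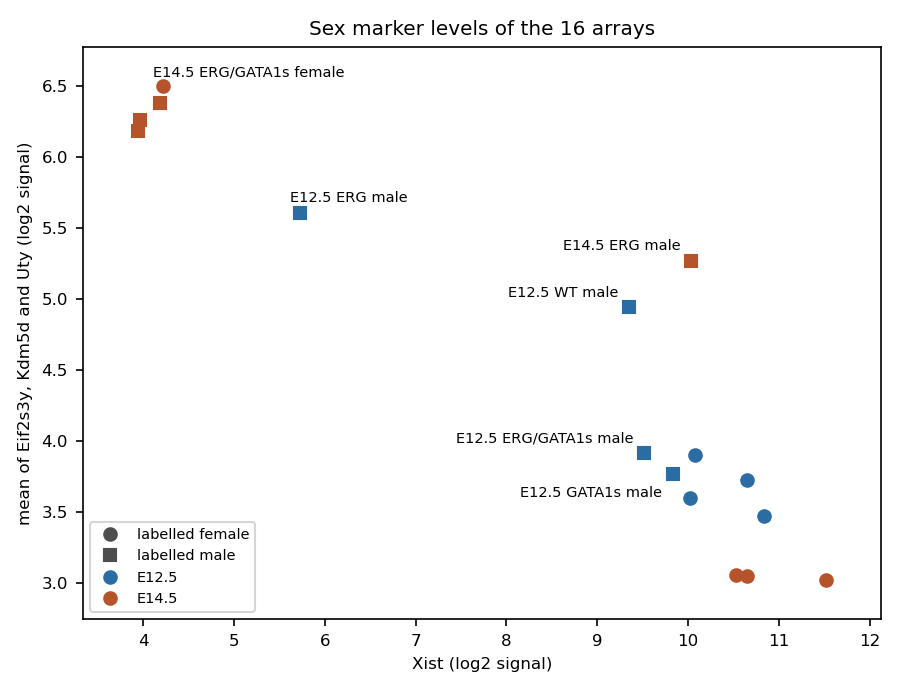
Xist signal (horizontal, log2) against the mean signal of Eif2s3y, Kdm5d and Uty (vertical, log2) in each of the 16 arrays, circles labelled female and squares labelled male. The E14.5 ERG/GATA1s array labelled female sits at 4.22 and 6.50, among the arrays labelled male, and 2 E12.5 squares sit among the circles.

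The first principal component held 52.6% of the variance of the test units and the second 13.9%. The 2 arrays of a group correlated least in E12.5 ERG/GATA1s, at 0.9769 across probe sets, and most in E14.5 ERG, at 0.9956. The E12.5 ERG/GATA1s array labelled male had the lowest SD over its probe sets, 2.03 against 2.13 to 2.25 in the others. It lay at -51 on the first component, against -26.6 for its partner. Where that group is compared below, counts without the partner rest on this array alone for the group. Such counts can reflect its own deviation.

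Which genes respond to the GATA1s allele was asked with GATA1s against WT over both stages. Genes of the platelet lineage were the main group to rise, among them Mmrn1, a carrier protein of platelet granules, the integrin Itgb3 and the lipoxygenase Alox12. Immediate early genes (Fosb, Jun, Fos), the neuropeptide Npy and the chemokine Ccl3 rose with them. The stress and immediate early list was chosen as genes that rise with cell dissociation and handling. A difference in handling between samples was not tested, here or below. Red cell genes such as Rhd and the spectrin Sptb fell, while Car1, a carbonic anhydrase of the same lineage, rose. In limma's test 620 of 16258 genes passed, 355 higher and 265 lower. The count was 147 without the E12.5 GATA1s array labelled female and 1055 without either E12.5 ERG/GATA1s array.

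Mmrn1 rose at least 8.35-fold (log2 3.06 ± 0.32, adjusted p = 0.000227, 4 of 4 pairs), Npy 7.31-fold (2.87 ± 0.26, adjusted p = 0.000153, 4 of 4 pairs) and Fosb 4.90-fold (2.29 ± 0.16, adjusted p = 2.62e-05, 4 of 4 pairs). AI506816, Ccl3, Klk1b22, Slc7a11, Car1, Cps1 and Serpinb2 completed the 10 largest rises, with log2 changes of 1.72 to 2.99. Cps1 was higher in 3 of its 4 pairs and the others in 4 of 4. The WT mean of Mmrn1 was 3.16 and that of AI506816 3.48 at E14.5, and that of Klk1b22 was as low as 2.94, below the level of 3.74 under which probe sets were taken as dim. Rises from such levels to levels above 3.74, here and below, can be smaller than the change in RNA, so they are read as "at least". Ear6 fell most (-1.77 ± 0.21, adjusted p = 0.000536, 4 of 4 pairs), followed by Mboat2 (-1.50), Ctse (-1.13), Spopl (-1.01), Tlcd1 (-1.01) and 6720489N17Rik (-1.01 ± 0.14, adjusted p = 0.00179). Sh2d4a, Atp10d, Myo1d and Slc26a1 fell by 0.98, 0.97, 0.95 and 0.94 on the log2 scale. The calls for Ctse, Tlcd1 and Slc26a1 were lost without the E12.5 WT array labelled male, among others, with adjusted p up to 0.217, 0.157 and 0.092. Gata2, which full-length GATA1 represses, rose by 0.69 ± 0.16 (adjusted p = 0.0306, 4 of 4 pairs). That call was lost without any of 5 arrays, with an adjusted p up to 0.166.

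Of the 24 measured megakaryocyte and platelet genes, 22 rose and 0 fell, and 23 rose when adjusted over the list alone. The list's median change was 1.07 and its camera adjusted p was 1.12e-33, but adjusted p = 0.142 with an estimated correlation. Alox12 rose by 1.34, Plek by 1.29 and Itgb3 by 1.26. Of 36 erythroid genes 6 fell and Car1 rose (1.76 ± 0.18), and 19 fell when adjusted over the list alone (camera adjusted p = 2.32e-10; adjusted p = 0.55 with an estimated correlation). Ppox (-0.63), Sptb (-0.61) and Rhd (-0.58) led the falls, and each of these calls was lost without the E12.5 WT array labelled male, among others. Stress and immediate early genes rose in 4 of 13 cases, and in 10 when adjusted over the list alone (camera adjusted p = 1.35e-08; adjusted p = 0.168 with an estimated correlation). Jun rose by 1.30, Atf3 by 1.05 and Fos by 0.92. Mean Jun signal was 9.61 in WT and 9.72 in GATA1s at E12.5, and 5.97 and 8.45 at E14.5. That of Fosb was 7.71 and 8.98, then 4.92 and 8.23. Of 27 cell cycle genes 27 were lower and 1, Aurkb (-0.44), passed. The p53 targets Sesn2 and Bbc3 rose by 0.55 and 0.51, and the interferon-response gene Oasl2 by 0.61. In the liver parenchyma list Afp fell by 0.43 on the log2 scale and Cps1 rose by 1.75. The calls for Bbc3, Oasl2, Aurkb and Afp were lost without 1, 3, 4 and 7 of the arrays, with adjusted p up to 0.0842, 0.0973, 0.118 and 0.105. Mean Afp signal was 11.03 in WT and 10.05 in GATA1s at E12.5, and 11.85 and 11.96 at E14.5.

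**Figure D2:**
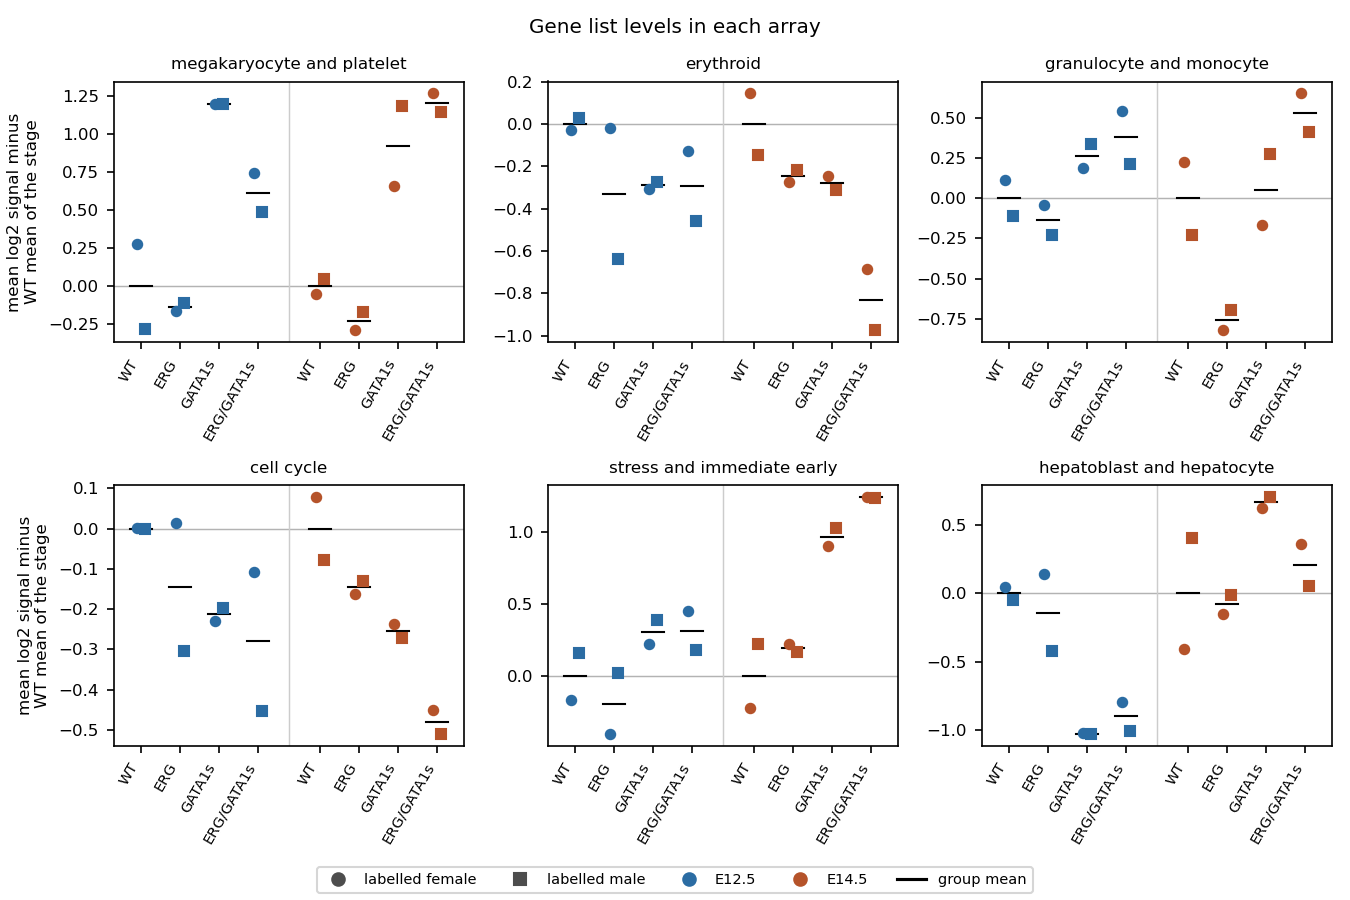
Mean log2 signal of 6 gene lists in each array, minus the WT mean of the same stage, for the 8 groups (circles labelled female, squares labelled male, bars the group means). The megakaryocyte and platelet list is above WT in GATA1s and ERG/GATA1s at both stages, and the hepatoblast and hepatocyte list lies 1.03 below WT in GATA1s at E12.5 and 0.67 above it at E14.5, where the WT array labelled female lies 0.409 below the WT mean and its partner 0.409 above it.

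By stage, GATA1s raised platelet genes at both. At E12.5 the genes of liver parenchyma (clotting and transport proteins made by hepatocytes) were lower: Serpind1, Vtn, Fgg, Fgb and Ambp fell. At E14.5 every measured gene of that list was higher than in WT, although only Cps1, the first enzyme of the urea cycle, passed, and the E14.5 WT arrays lay far apart on the list. At E12.5, 217 genes passed (134 higher, 83 lower). The count was 0 without the E12.5 WT array labelled male or either E12.5 GATA1s array, and 461 without either E12.5 ERG/GATA1s array, so no call at E12.5 held without each array in turn. At E14.5, 174 passed (123 higher, 51 lower), with 42 without the E14.5 WT array labelled female and 956 without the E14.5 WT array labelled male. With only the arrays of the groups compared, where the spread rests on fewer arrays, 0 passed at either stage.

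The 5 largest rises at E12.5 were Mmrn1 (2.89 ± 0.45), Serpinb2 (2.24), Ptgs2 (2.19), Npy (2.13) and Serpinb10 (1.94), with adjusted p from 0.00651 to 0.0365 and each in 2 of 2 pairs. Cpn1 (-1.75), Serpind1 (-1.68), Ear6 (-1.64), Vtn (-1.61) and Cpm (-1.57) fell most. Of 24 platelet genes 17 rose (23 adjusted over the list alone), among them Gp5 (1.41) and F2rl2 (1.40). Of 21 liver parenchyma genes 10 fell (18 adjusted over the list alone), with a median of -1.09; the list's adjusted p = 0.308 with an estimated correlation. At E14.5, AI506816 rose by 4.03 ± 0.49, Npy by 3.61 ± 0.36, Cps1 by 3.60 ± 0.25, Fosb by 3.31 ± 0.23 and Ccl3 by 3.26 ± 0.26, each in 2 of 2 pairs. Mboat2 (-2.08), Ctse (-2.08), Ear6 (-1.89) the interferon-response gene Rsad2 (-1.85) and Ccdc92b (-1.38, adjusted p = 0.00328) fell most. The calls for Ctse, Ear6, Rsad2 and Ccdc92b were each lost without the E14.5 WT array labelled female, and the first 3 also without a GATA1s array, with adjusted p up to 0.162, 0.0886, 0.198 and 0.0566; that for Mboat2 held without any 1 array. Platelet genes rose in 9 of 24 cases (19 adjusted over the list alone) and stress genes in 5 of 13 (9 adjusted over the list alone), led by Fosb, Jun (2.48) and Atf3 (1.81). The liver parenchyma list had a median of 0.56, with adjusted p = 0.551 with an estimated correlation. Its mean signal was 9.317 and 10.135 in the WT arrays labelled female and male, and 10.352 and 10.434 in GATA1s. Its mean shift of 0.67 was 0.19 without the WT array labelled female, where the call with the preset correlation was lost (adjusted p = 0.0625), and 1.14 without the WT array labelled male.

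What ERG alone changes was asked with ERG against WT. Over both stages a small set rose, led by Nrip3, a nuclear receptor interacting protein, the GTPase Gem, the sialic acid enzyme Cmah and the integrin Itgb7. The stem cell factor Gata2 and the leukotriene enzyme Alox5 were also higher. Cd82, Vsir and Pld4, genes of myeloid and lymphoid cells, fell. The rises came from E14.5: in the E12.5 arrays these genes lay near WT. Over both stages 46 genes passed, 39 higher and 7 lower, a share of 84.8% higher that was 73.6% after a further quantile normalization and 100% after centring each array. Leaving out 1 array gave 5 calls (without the E12.5 WT array labelled male) to 134 (without the E12.5 ERG array labelled female).

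Nrip3 rose 3.77-fold (1.92 ± 0.16, adjusted p = 0.000246, higher in 2 of 4 pairs), Gem 3.46-fold (1.79 ± 0.17, adjusted p = 0.000439, 4 of 4 pairs), Cmah 2.72-fold (1.44 ± 0.14, adjusted p = 0.000416, 3 of 4 pairs) and Itgb7 2.20-fold (1.14 ± 0.12, adjusted p = 0.000557, 3 of 4 pairs). These 4 calls and that of Cnrip1 (1.08) held without any 1 array. With only the WT and ERG arrays 0 genes passed, and the 5 calls had adjusted p of 0.0553 to 0.135. The calls for Aqp8 (1.70), Alox5 (1.16), Sla2 (1.14), Septin1 (1.07), Cpne7 (1.05) and Gata2 (1.04 ± 0.16, adjusted p = 0.0168) did not, and each was lost without the E14.5 ERG array labelled female, with adjusted p up to 0.258. The 7 falls were Cd82 (-1.23), Vsir (-0.68), Slc24a5 (-0.66), Pld4 (-0.66), Trpv2 (-0.62), Plac8 (-0.59) and Ctsf (-0.53), in 4 of 4 pairs and with adjusted p from 0.0283 to 0.0481. Each was lost without the E12.5 ERG array labelled male. No list member passed besides Gata2 and Alox5. All 23 granulocyte and monocyte genes were lower (11 adjusted over the list alone, adjusted p = 0.21 with an estimated correlation).

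At E12.5, limma called 0 genes in ERG against WT, with 666 at an unadjusted p under 0.05. Without the E12.5 ERG array labelled female it called 9. The genes of smallest p, Brox (0.87), Nefm (-0.51), Rps6ka6 (0.49), Fbxo42 (-0.61) and Polr2k (-0.70), each had an adjusted p of 0.957 and did not pass. On simulated data of this comparison the test recovered 77% of genes changed 2-fold and 98% of those changed 4-fold. The simulated noise had the same spread in every group and was independent between genes. It can therefore overstate the sensitivity at E12.5.

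At E14.5, 275 genes passed in ERG against WT, 193 higher and 82 lower. Nrip3 rose 15.5-fold (3.95 ± 0.23, adjusted p = 1.88e-06), Gem 11.1-fold (3.47 ± 0.25, adjusted p = 8.07e-06), Aqp8 8.46-fold (3.08 ± 0.34), Slamf1 6.57-fold (2.71 ± 0.41) and Cmah 5.58-fold (2.48 ± 0.19), each in 2 of 2 pairs. Gata2 rose by 2.37 ± 0.23 (adjusted p = 0.000198), Alox5 by 2.22 and Myc by 0.75. Some genes of granule proteins fell: Ear6 (-1.70), Cpa3 (-1.60), Ctsg (-1.51), Epx (-1.42), Elane (-1.30), Mpo (-1.27) and Prg2 (-1.25). Runx1t1 (-1.83) and Cd82 (-1.52) fell too. The mast cell, basophil and eosinophil list had a mean change of -0.25. In it Alox5, Srgn and Cd63 were higher, and Tpsb2 and Prss34 lay near WT. Of 23 granulocyte and monocyte genes 6 fell, 15 when adjusted over the list alone, and all 23 were lower (camera adjusted p = 4.6e-20; adjusted p = 0.112 with an estimated correlation). Platelet genes went both ways, with Rgs18 (-1.45), Itgb3 (-1.23) and Ppbp (-1.04) among 5 that fell while Gp5 rose (1.35). The macrophage genes Csf1r (-0.81) and Mertk (-0.71) and the lymphoid gene Igll1 (-0.85) fell. The count was 31 without the E14.5 ERG array labelled female, 73 without the WT array labelled female and 504 without the WT array labelled male, and each of these falls was lost without the E14.5 ERG array labelled female. So were the rises of Slamf1, Myc and Gp5, with adjusted p up to 0.0764, 0.194 and 0.32. With only the arrays of these 2 groups 0 genes passed.

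**Figure D3:**
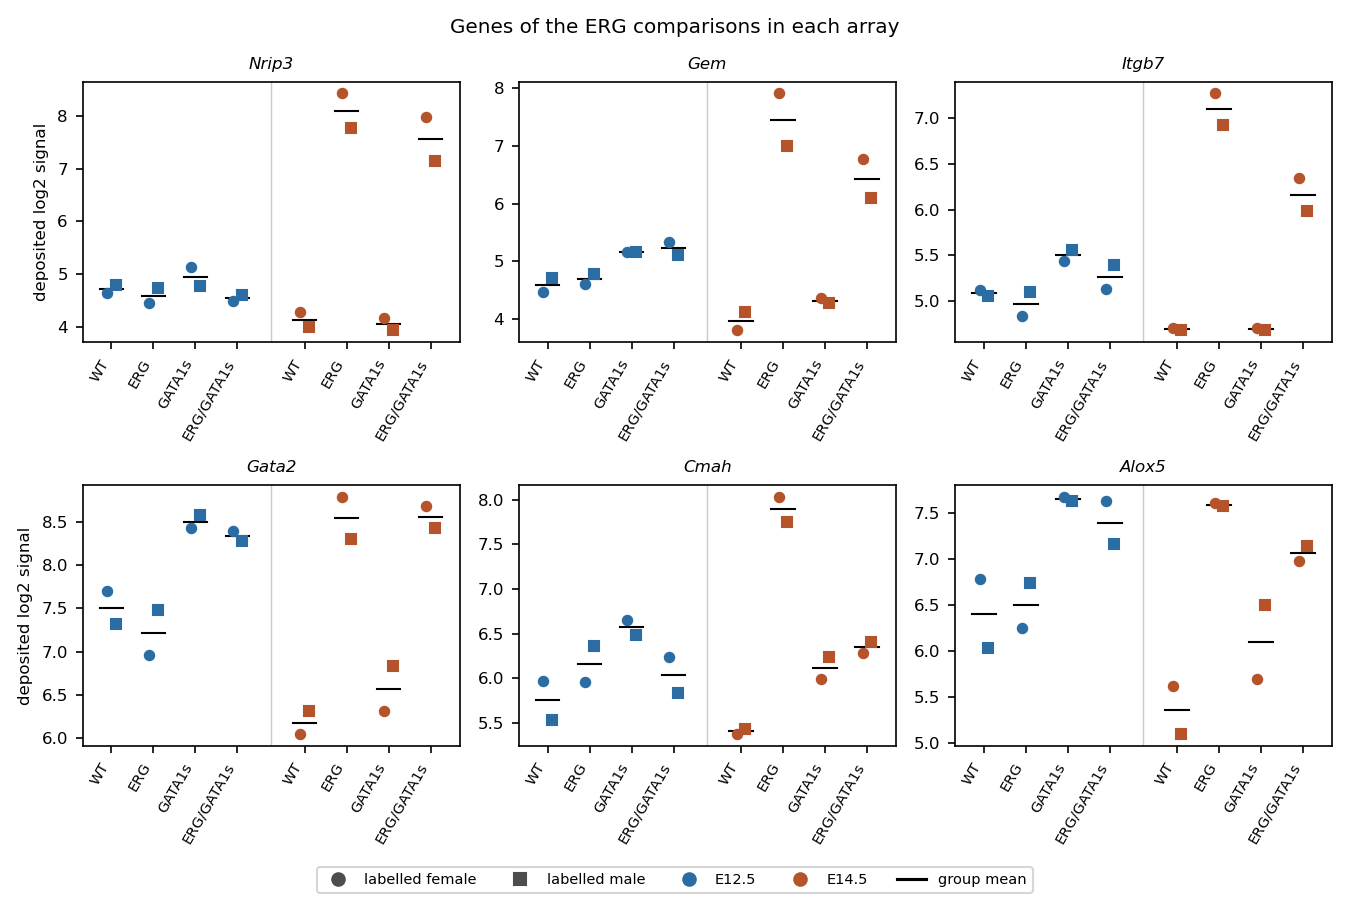
Deposited log2 signal of Nrip3, Gem, Itgb7, Gata2, Cmah and Alox5 in each array for the 8 groups (circles labelled female, squares labelled male, bars the group means). At E14.5 the ERG arrays lie above WT in all 6 panels, by 3.95 for Nrip3 and 2.48 for Cmah, and at E12.5 they lie near WT.

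Whether the genotype effects differ between stages was tested with 1 F test per gene over the 3 stage by genotype terms. Genes raised by ERG at E14.5 alone (Nrip3, Itgb7, Gem, Gata2) and genes raised more by GATA1s at E14.5 (Fosb, Cps1) had the smallest p. In all 393 genes passed, from 2.18e-05 for Nrip3 to 0.000992 for Gata2 among the first 6 adjusted p. Tested per genotype, the effect differed in 37 genes for ERG, 36 of them more positive at E14.5, in 57 for GATA1s (50 more positive) and in 99 for ERG/GATA1s (66 more positive). The ERG/GATA1s arrays had female sex markers at E12.5 and male ones at E14.5, so their stage difference is confounded with sex. Leaving out 1 array gave 109 (without the E12.5 GATA1s array labelled male) to 1055 (without the E14.5 WT array labelled male).

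What both alleles change together was asked with ERG/GATA1s against WT, the genotype comparison with the most calls over both stages in the fit of all 16 arrays. Platelet genes (Mmrn1, Itga2b, Treml1, Plek) rose and red cell genes (Uros and Tfrc of haem synthesis and iron uptake, Rhd, Cldn13) fell. Proliferation genes such as Ccne1 and Mki67 fell, and the neutrophil proteins S100a8 and S100a9 rose. Gata2, Runx1 and Fli1, which act together in blood stem cells, rose and their partner Lmo2 fell. Over both stages 1720 genes passed, 660 higher and 1060 lower. The count was 4048 without the E12.5 ERG/GATA1s array labelled female, 1050 without its partner, and 788 and 1024 without the E14.5 ERG/GATA1s arrays labelled female and male. Without the E12.5 WT array labelled male it was 827.

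AI506816 rose by 3.09 ± 0.34, Mmrn1 by 2.74 ± 0.32, Npy by 2.52 ± 0.26, Ccl3 by 2.27 ± 0.18 and Fosb by 2.12 ± 0.16, each in 4 of 4 pairs with adjusted p from 6.18e-05 to 0.000273. Hamp (1.98), Ndrg2 (1.75) and Rgs1 (1.73) followed, with the small non-coding RNAs Rny1 (1.73 ± 0.27, adjusted p = 0.00162) and Rnu12 (1.73 ± 0.29, adjusted p = 0.00249). The list members Car1 and Jun rose by 1.69 and 1.66. Hamp was higher in 2 of 4 pairs. The WT means of Mmrn1, AI506816 and Rgs1 (3.02) at E14.5 were below 3.74, so these rises too are "at least". Hamp was dim in both groups at E12.5 (3.70 in WT, 3.49 in ERG/GATA1s), and its rise comes from E14.5 (4.16 and 8.34). Fn3k fell most (-2.31 ± 0.28, adjusted p = 0.000421, 4 of 4 pairs), then its neighbour Fn3krp (-1.87), Tac2 (-1.79), Sh3yl1 (-1.74) and Endod1 (-1.73). Ear6, Mgll, Ctse, Pdia2 and Btnl10 fell by 1.55, 1.52, 1.52, 1.51 and 1.47 on the log2 scale. The calls for Tac2, Mgll and Cldn13 were lost without the E12.5 ERG/GATA1s array labelled male, with adjusted p of 0.057 to 0.0636 at most.

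Of 24 platelet genes 20 rose, and Ppbp fell by 0.65 on the log2 scale; 21 rose when adjusted over the list alone (adjusted p = 0.209 with an estimated correlation). Of 36 erythroid genes 27 fell and Car1 rose, with 32 falling when adjusted over the list alone (camera adjusted p = 5.92e-19; adjusted p = 0.288 with an estimated correlation). Uros fell by 1.13, Cldn13 by 1.11, Rhd by 1.05 and Tfrc by 1.04 on the log2 scale. Cell cycle genes fell in 15 of 27 cases, 25 adjusted over the list alone, and granulocyte and monocyte genes rose in 9 of 23, 13 adjusted over the list alone (adjusted p = 0.288 and 0.294 with an estimated correlation). Stress genes rose in 10 of 13 cases (adjusted p = 0.209 with an estimated correlation), interferon-response genes in 4 of 11, with Oasl2 at 0.62 and Ifit1 at 0.51, and endothelial genes in 4 of 16, led by Pecam1 (0.62). Ifit1 was dim in WT at both stages (mean 3.42 at each) and in ERG/GATA1s at E12.5 (3.62), so its rise comes mostly from E14.5 (4.22). Gata2 rose by 1.60 ± 0.16 and Runx1 by 0.80, while Fli1 (0.48) was lost without 5 of the arrays and Lmo2 fell by 0.53 on the log2 scale. In the liver parenchyma list 4 genes fell, among them Hnf4a (-0.57) and Apob (-0.56), and Cps1 rose. The p53 target Bbc3 rose by 0.68 and the stellate cell gene Ngfr by 0.48. The calls for S100a9, Hnf4a, Apob and Ngfr were lost without 3, 5, 9 and 5 of the arrays, with adjusted p up to 0.0755, 0.116, 0.194 and 0.0947. Mean Apob signal was 7.66 in WT and 6.60 in ERG/GATA1s at E12.5, and 9.54 and 9.47 at E14.5; that of Hnf4a was 7.23 and 6.35, then 7.88 and 7.64. Of 12 fetal programme and IGF genes 1 rose and 1 fell (median -0.01), of 9 lymphoid genes 1 fell, of 10 GATA1-repressed genes 2 rose and 1 fell, of 10 mast cell, basophil and eosinophil genes 2 rose, and of 3 globins 1 rose.

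At E12.5, 1 gene passed in this comparison, Tmem267 (-1.36 ± 0.18, adjusted p = 0.0439), with 2564 at an unadjusted p under 0.05. That call was lost without any of 12 arrays (adjusted p up to 0.564). Next by p, G2e3 (-1.48), Serpina6 (-0.82), Cdhr2 (-1.04) and 6720489N17Rik (-1.14) had adjusted p of 0.123 to 0.138 and did not pass. Without the E12.5 ERG/GATA1s array labelled female far more genes passed. The group then rests on the array labelled male, so those calls can reflect that array's own deviation and not genotype. At E14.5, 1489 passed, 726 higher and 763 lower, with 507 without the E14.5 ERG/GATA1s array labelled female, 662 without its partner and 776 without the E14.5 WT array labelled female. Hamp rose by 4.18 ± 0.56, AI506816 by 3.99, Npy by 3.78, Fosb by 3.72 and Ccl3 by 3.71, and Fn3k (-3.84 ± 0.40), Fn3krp (-2.75), Snx22 (-2.74), Runx1t1 (-2.66) and Endod1 (-2.65) fell, each in 2 of 2 pairs. Of 36 erythroid genes 29 fell, led by Cldn13 (-1.76), Dmtn (-1.67) and Uros (-1.55), and of 24 platelet genes 19 rose. The Cldn13 call was lost without the E14.5 ERG/GATA1s array labelled female (adjusted p = 0.0732). With only the arrays of these 2 groups 0 genes passed at E14.5. Both E14.5 ERG/GATA1s arrays had male sex markers and only 1 of the WT arrays did, so these effects can include one of sex.

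**Figure D4:**
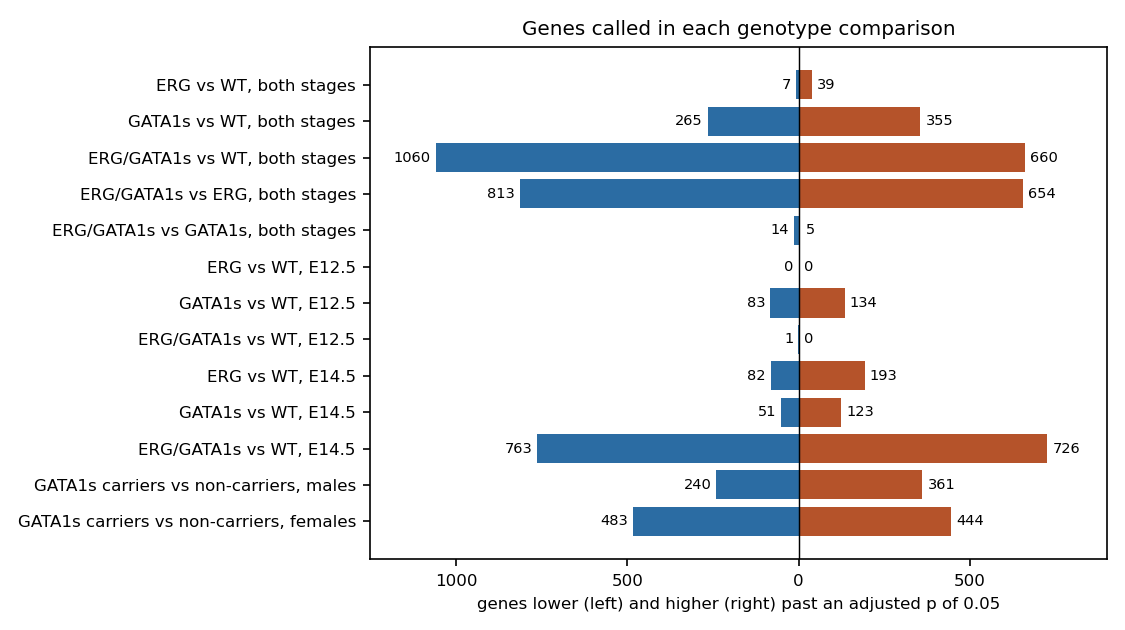
Number of genes past an adjusted p of 0.05 in each genotype comparison, lower to the left and higher to the right. ERG/GATA1s against WT over both stages has 1060 lower and 660 higher, and ERG against WT at E12.5 has 0.

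The GATA1s allele on the ERG background was read from ERG/GATA1s against ERG. Platelet and granulocyte genes rose together: Itgb3, Rgs18 and Alox12 on one side, S100a8, S100a9, Ngp and Ctsg on the other. The granulocyte and monocyte list had a mean change of 0.90 here. It was lower in ERG than in WT (-0.45), so part of this rise reflects low levels in ERG. In GATA1s against WT its mean change was only 0.16 (median 0.07). The platelet list had mean changes of 1.09 here and 1.06 in GATA1s against WT. Among progenitor genes Flt3, Cd34 and Angpt1 rose, and of red cell genes Tfrc and Rhd fell. The 24 measured stem and progenitor genes had a mean change of only 0.13, and Myb and Tek were lower at both stages. The E14.5 ERG mean of Angpt1 was 3.50, below 3.74, so its rise is read as "at least". In this comparison 1467 genes passed, 654 higher and 813 lower. The count was 547 without the E14.5 ERG array labelled male and 3954 without the E12.5 ERG/GATA1s array labelled female. AI506816 (3.13 ± 0.34), Mmrn1 (3.01 ± 0.32), Npy (2.49), Fosb (2.38), Serpinb10 (2.02), Itgb3 (1.95) and Ccl3 (1.82) rose in 4 of 4 pairs with adjusted p from 8.24e-06 to 0.000944. AI506816 and Mmrn1 rose by at least these amounts, as their E14.5 ERG means were 3.73 and 3.24. The small non-coding RNAs Snord118 (2.58 ± 0.37, adjusted p = 0.00104), Rnu12 (2.01) and Rny1 (1.90) were among the 10 largest rises. Ccnb1ip1 (-2.79 ± 0.50), Muc6 (-1.40), Mns1 (-1.33), Endod1 (-1.24), Sh3yl1 (-1.23), Fn3krp (-1.23), Them6 (-1.18), Atp10d (-1.16), 1700006J14Rik (-1.16) and Zfp760 (-1.07) fell. Ccnb1ip1 varied widely within some groups, with an SD of 1.3 in E12.5 ERG and 2.6 in E14.5 WT, so the size of its fall is uncertain. The Fn3krp call was lost without the E12.5 ERG/GATA1s or the E14.5 ERG array labelled male (adjusted p up to 0.0694). Of 24 platelet genes 19 rose (20 adjusted over the list alone), of 23 granulocyte and monocyte genes 17 (22 adjusted over the list alone), and of 13 stress genes 7 (11 adjusted over the list alone), each list with adjusted p = 0.0864 with an estimated correlation. S100a8 rose by 1.72, S100a9 by 1.67, Ngp by 1.48 and Ctsg by 1.44. Tfrc, Flt3 (0.69) and Angpt1 (0.59), but not Cd34 (0.64), were lost without the E12.5 ERG/GATA1s array labelled male, among others, with adjusted p up to 0.126, 0.0639 and 0.207.

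ERG on the GATA1s background was read from ERG/GATA1s against GATA1s. Nrip3 and Gem, raised by ERG alone, were raised here too, with the chemokine Ccl2 and the calcium channel subunit Orai2. The platelet chemokine Ppbp and Endod1 fell. Only 19 genes passed, 5 higher and 14 lower, with 1264 at an unadjusted p under 0.05. The share of higher calls was 26.3%, and 43.8% after a further quantile normalization. Nrip3 rose by 1.55 ± 0.16 (adjusted p = 0.00333, 2 of 4 pairs), Ccl2 by 1.11, Gem by 1.08, Sash3 by 0.66 and Orai2 by 0.62. Syt14 (-1.34), Prokr1 (-1.04), Xpo7 (-0.97), Endod1 (-0.96), Tnfrsf13c (-0.83), F930017D23Rik (-0.83), Abcb11 (-0.81), Ccrl2 (-0.80), Ppbp (-0.77) and Fam214b (-0.67) led the falls. Gata2 (0.90) missed the threshold (adjusted p = 0.0547). No call held when any 1 array was left out: 0 genes passed without the E12.5 GATA1s array labelled male, and 44 without either E14.5 WT array.

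Whether ERG acts differently with GATA1s was tested with the ERG by GATA1s interaction. Cmah, raised by ERG alone, and Plac8, lowered by ERG alone, responded differently to ERG in arrays with GATA1s. Only these 2 genes passed, with 714 at an unadjusted p under 0.05: Cmah (-1.59 ± 0.19, adjusted p = 0.0166) and Plac8 (1.09 ± 0.15, adjusted p = 0.0291). The share of higher calls, 50%, was 66.7% after a further quantile normalization and 0% after centring. Prtn3 (1.24, adjusted p = 0.0649), Nkg7 (1.29, 0.121) and Mpo (0.98, 0.121) did not pass. Of 23 granulocyte and monocyte genes 22 had a positive interaction, 16 past the threshold adjusted over the list alone (camera adjusted p = 4.5e-33; adjusted p = 0.102 with an estimated correlation). Leaving out 1 array gave 0 calls (without the E12.5 WT array labelled male, among others) to 20 (without the E14.5 WT array labelled male). The Cmah call was lost without any of 5 arrays and that of Plac8 without any of 12, with adjusted p up to 0.135 and 0.183.

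Comparisons that share no array were set side by side. The GATA1s effect without ERG and with ERG shared 250 higher genes (14.3 expected for independent lists) and 185 lower genes (13.3 expected), and Pearson's r across genes was 0.73. Genes are not independent replicates, and compared lists share 1 estimate of the spread per gene. So r, the expected counts and Fisher's exact p are descriptions, here and below. The ERG effect without and with GATA1s shared 3 higher genes (0.012 expected) and 0 lower, with r of 0.32. The 3 were shared at an adjusted Fisher's exact p of 2.54e-07. The GATA1s effect at E12.5 and E14.5 shared 32 higher and 4 lower genes (1.01 and 0.26 expected, r of 0.25). With 0 calls for ERG and 1 for ERG/GATA1s at E12.5, these effects had next to nothing to share between stages, and both shared 0, with r of 0.02 and 0.38.

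The change with stage, 8 arrays against 8, gave more calls than any genotype comparison, though not the largest changes: Hamp, AI506816 and Nrip3 rose more in a genotype at E14.5 and Fn3k fell more. Hepatocyte genes, which mark the maturing liver, rose from E12.5 to E14.5, and so did the macrophage genes Cd5l, Vcam1 and Adgre1. The embryonic globins Hbb-bh1, Hba-x and Hbb-y fell, as did the immediate early genes Jun, Fosb and Egr1 and the progenitor genes Cd34, Kit and Myb. In all 9135 genes passed, 4718 higher and 4417 lower at E14.5. Serpina1c rose by 3.90 ± 0.16, Aadac by 3.79 ± 0.19, Apoh by 3.49 ± 0.21, Fabp1 by 3.40 ± 0.15 and Cd5l by 3.29 ± 0.13, with adjusted p from 2.16e-09 to 4.24e-08. Rgn (3.16), Gsta3 (3.16), Mgst1 (3.08), Bex1 (3.03) and Ahsg (2.90) came next. The E12.5 means of Cd5l and Rgn were below 3.74 in all 4 genotypes, so both rose by at least these amounts. Hbb-bh1 (-2.84 ± 0.14), Hsd3b6 (-2.70 ± 0.08), Ccl3 (-2.48), Jun (-2.41), AY036118 (-2.35), Hba-x (-2.16), Hormad1 (-1.94), Epx (-1.90) and the small non-coding RNA Rnu3a (-1.90) fell most. Xist fell too (-2.12 ± 0.79, adjusted p = 0.0353), a call lost without any of 8 arrays; its level parts arrays by sex markers, which oppose some labels. All 21 liver parenchyma genes rose (median 1.84), 13 of 14 macrophage genes rose and 3 of 3 globins fell (each adjusted p = 0.231 with an estimated correlation). Of 16 endothelial genes 10 rose, of 15 stellate genes 8, of 11 interferon-response genes 7, and of 24 stem and progenitor genes 16 fell.

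Labelled sex was compared with limma over the 8 groups. Xist was lower (-2.74 ± 0.79) and Eif2s3y (1.93 ± 0.45), Kdm5d (1.09) and Uty (1.48) higher in arrays labelled male, with adjusted p of 0.221 to 0.223, so 0 genes passed, with 2278 at an unadjusted p under 0.05. Smallest in p were Piga (-0.47), Trim23 (-0.45), Zfp654 (-0.35), Slc38a9 (-0.56) and Dennd4a (-0.54), each with an adjusted p of 0.221. Because 3 arrays carry markers that oppose their label, this comparison does not measure sex. The GATA1s effect by labelled sex also gave 0 genes, with 379 at an unadjusted p under 0.05; smallest in p were Them6 (-0.72), 1700054O19Rik (0.87), Hormad1 (-2.03), Dimt1 (0.55) and Mir680-2 (0.97), each with an adjusted p of 0.998. Gata1 lies on the X chromosome, which is why carriers were also compared within each label. All 3 arrays whose markers oppose their label carry GATA1s. These comparisons by label, and their shared genes, therefore cannot show an effect of sex or of X-linked dosage. Among arrays labelled male 601 genes passed (361 higher, 240 lower), and among those labelled female 927 (444 higher, 483 lower). They shared 261 higher and 142 lower genes (9.86 and 7.13 expected), with r across genes of 0.78. AI506816 (3.53 and 2.59), Mmrn1 (3.42 and 2.65), Npy (2.96 and 2.40) Fosb (2.46 and 2.21), Ccl3 (1.93 and 1.86) and the small non-coding RNA Snord118 (2.36 and 1.75) rose in arrays labelled male and female, and Ear6 (-1.30 and -1.23) and Mboat2 (-1.27 and -1.28) fell in both. In arrays labelled male, Serpinb2 (2.11), Serpinb10 (2.00), Slc7a11 (1.86) and F13a1 (1.80) rose. Ccnb1ip1 (-2.71), Hormad1 (-1.92), Them6 (-1.33), Sh2d4a (-1.18), Fn3krp (-1.11), Atp10d (-1.07), Dnajb3 (-1.04) and Mns1 (-1.03) fell there. Ccnb1ip1 differed widely between the 2 arrays of some groups, as given above. In arrays labelled female, Rnu12 (1.69), Rgs1 (1.66), Cps1 (1.58) and Klk1b22 (1.57) rose. Rbm12b2 (-1.36), Ctse (-1.34), Sh3yl1 (-1.29), 6720489N17Rik (-1.14), Gm7265 (-1.11), Mindy2 (-1.10), Pot1b (-1.09) and Muc6 (-1.09) fell there. The calls for Fn3krp in arrays labelled male and Snord118 in those labelled female were lost without 10 and 6 of the arrays, with adjusted p up to 0.218 and 0.0973. In arrays labelled male the calls for Hormad1 and Ear6 were also lost without 1 array or another, and in those labelled female the calls for Rbm12b2, Ctse, Sh3yl1, Ear6, Mindy2 and Pot1b, with adjusted p of 0.0524 to 0.0875 at most. The counts ran from 155 (without the E12.5 WT array labelled male) to 1473 in arrays labelled male, and from 189 (without the E12.5 GATA1s array labelled female) to 3355 in arrays labelled female, both highest without the E12.5 ERG/GATA1s array labelled female.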

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

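The tests of the sex markers and those of the hepatocyte genes were chosen after their results had been seen; the tests of the ERG response and the other splits of the arrays were written before.

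Several results stood out because a test of the difference between groups passed. Genotype effects differed between E12.5 and E14.5 in 393 genes: 37 for ERG, 57 for GATA1s and 99 for ERG/GATA1s, tested separately. The F test's adjusted p was 2.18e-05 for Nrip3, 0.000179 for Itgb7, 0.000743 for Fosb, 0.000743 for Gem, 0.000919 for Cps1 and 0.000992 for Gata2. The ERG effect differed with GATA1s in 2 genes, Cmah (-1.59) and Plac8 (1.09). With the preset correlation 5 lists passed in that interaction and 4 in the GATA1s effect by labelled sex, and none of them passed with an estimated correlation.

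Probe sets without a gene symbol, which the comparisons leave out, also held signal. Of 2923 above the dim filter, 2 were called in ERG against WT (2 higher, 0 lower), 56 in GATA1s (32 higher, 24 lower) and 200 in ERG/GATA1s (121 higher, 79 lower), over both stages. The gap test for single arrays that lie far from the rest of their group needs groups of at least 4 and was not run, as every group held 2.

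The ERG response was called at E14.5 and not at E12.5. If lower sensitivity at E12.5 hid a response of the same size, the 275 genes called at E14.5 would shift at E12.5 by at least 0.54, 50% of their E14.5 shift of 1.09. Their mean signed shift was 0.04 (95% interval -0.16 to 0.24), which argues against a response of that size. If the E14.5 WT arrays alone gave the calls, the same genes would not shift in ERG/GATA1s against GATA1s at E14.5. That comparison holds no WT array, and the genes shifted by 0.51 (0.31 to 0.71), below 1.09. The 1.09 comes from the arrays that chose the genes, so it can overstate the response, and the bound of 0.54 with it. A bound set from 0.51 would lie close to the upper end of 0.24 at E12.5, so a smaller shared response is less clearly opposed. A response to ERG that depends on stage stays open as a hypothesis, with a difference between the embryos of the E12.5 and E14.5 ERG groups untested.

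Hepatoblast and hepatocyte genes shifted by -1.03 (95% interval -1.71 to -0.35) in GATA1s at E12.5 and by 0.67 (-0.01 to 1.35) at E14.5, where it was 0.19 (-0.34 to 0.72) without the WT array labelled female and 1.14 without its partner, so a deviant WT array stays open as a cause. Older GATA1s embryos at E14.5 would lower the embryonic globins by 1.3 on the log2 scale, scaled by the stage difference in the ERG arrays (by 0.69 with that of all genotypes). The globin shift was 0.28 (-0.22 to 0.78). Without that WT array it was 0.49 (-0.11 to 1.10) against -0.37 or -0.19 needed. This argues against age as the whole cause only if the GATA1s allele itself leaves the globins unchanged, which was not tested. The erythroid list was lower in GATA1s at E14.5 (mean change -0.28), so the globin test cannot decide. Younger embryos at E12.5 cannot be told apart from other causes: the globin shift was -0.26 (-0.76 to 0.24) against 2.01 needed (1.06 with all genotypes), but that would put the globins at 14.15 (13.19), above or near the highest deposited value of 13.32, and no stage before E12.5 was measured to show that they are higher there, so the bound set for this test was wrong. A different share of liver parenchyma cells in the suspension could account for both shifts: 0 of 21 members moved against the list by over 2 SE, and 21 of 21 lay on its side at each stage. That count was largely known when the test was chosen, and a shared regulation of these genes would look the same, so it decides nothing between them.

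Xist and Y-linked levels opposed the labelled sex in 3 arrays. A swap between 2 arrays of a stage needs a partner with the opposite mismatch. No array labelled female at E12.5 had male markers, which argues against such a swap for the 2 E12.5 arrays. At E14.5 the lack of a partner rests on the cutoff set for a mismatch. The E14.5 ERG array labelled male fell just short of it (Xist minus Y-linked signal 4.757), so a swap there is not excluded. A wrong label or an exchange with a sample outside the series needs no partner and was not tested. RNA of both sexes in one sample could account for 2 other arrays, E12.5 WT and E14.5 ERG labelled male, which held Xist within 2 of the median of 10.65 and Y-linked levels over 1 above the median of 3.48 of 7 arrays labelled female. A pool of embryos, maternal cells or carry-over between samples would each give this, and no test parted them. No biological explanation was tested.

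Chance was tested by splitting the arrays in other ways and refitting, on the 8 arrays alone where 4 were compared with 4. Those fits held additive terms for stage, labelled sex and the split (stage, ERG and the split for carriers), so their real counts differ from those of all 16 arrays and from those with 1 mean per group. The real split called the most genes for GATA1s against WT (230, highest other split 1) and ERG/GATA1s against WT (537, 0). It also did for ERG/GATA1s against ERG (495, 0) and carriers labelled male (182, 1). Other splits mix genotypes, so a genotype effect widens their spread and lowers their counts. In each of these, 1 of 33 splits, the real one, gave as many genes. That share argues against chance for each comparison taken alone, but 33 splits cannot give a smaller one. The same share held for ERG/GATA1s against GATA1s, but with 1 gene against 0 it decides little. For stage the real split also called the most genes (8887, highest other 7098). There 1 of 100 drawn splits gave as many, which argues against chance. Where those fits called 0 genes every split gave as many, so the count tests nothing and chance is left neither excluded nor shown: ERG against WT (highest other 0, 33 of 33 splits), carriers labelled female (1, 33 of 33), labelled sex (2, 98 of 98) and the GATA1s effect by labelled sex (0, 100 of 100). For the ERG by GATA1s interaction (2 genes), 16 of 100 splits gave as many and the highest gave 534. These splits redrew the genotype labels, so a drawn split can line up with a genotype effect and call many genes. What the split of 534 separates was not tested. The count therefore cannot decide, and chance was not excluded.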

How the results depend on the processing

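Leaving out the 3 arrays whose sex markers oppose their label and using a Y-linked level as covariate were chosen after seeing the data; all other alternatives were planned. Counts of calls and many named calls depend on single arrays or settings; directions of named genes did not. Of 352 named gene results 319 passed; none reversed, 200 passed without any 1 array and 121 under every other alternative run for them. Of these 121, 37 were changes with stage, 24 of GATA1s, 23 of ERG/GATA1s, 22 of ERG/GATA1s against ERG, and 9 and 6 of carriers labelled male and female. None were left for ERG over both stages or at E14.5, GATA1s or ERG/GATA1s at a single stage, ERG/GATA1s against GATA1s or the interaction. Not all were run for each: 239 of the 319 had a value with only the arrays compared, and 279 without a sex term, with the sex by GATA1s term or with the Y-linked covariate. Of 3627 values under those alternatives 3089 kept their side of the threshold and 538 lost the call; leaving out 1 array, 4500 of 5104 kept it and 604 lost it. The cause of the changes below was not tested, except that leaving out arrays or using only those compared leaves fewer arrays and a less certain spread. A group left with 1 array is assumed to vary like the others. Array signal near background (3.74) limits what dim genes can show.

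Counts that moved by over 1.5 times, against those of all 16 arrays in the report, were as follows. With no filter on dim probe sets, where more genes are adjusted for, they were ERG against WT 28, ERG/GATA1s against GATA1s 4, GATA1s at E12.5 140, ERG/GATA1s at E12.5 0 and effects that differ between stages 242. After a further quantile normalization they were ERG/GATA1s against GATA1s 32, GATA1s at E12.5 416 and ERG/GATA1s at E12.5 7, of which 71.4% were higher. With each array centred on its median they were ERG 20, GATA1s 401, ERG/GATA1s against GATA1s 6, the interaction 1, GATA1s at E12.5 108 and ERG/GATA1s at E12.5 0. With only the arrays of the groups compared they were ERG 0, ERG/GATA1s 1132, ERG/GATA1s against GATA1s 52, GATA1s at E12.5 0, ERG/GATA1s at E12.5 319, ERG at E14.5 0, GATA1s at E14.5 0 and ERG/GATA1s at E14.5 0. With arrayWeights they were ERG/GATA1s 585, ERG/GATA1s against ERG 974, ERG/GATA1s against GATA1s 0, GATA1s at E12.5 512, ERG/GATA1s at E12.5 0, effects that differ between stages 628 and carriers labelled female 1710.

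With the sex by GATA1s term they were ERG 27, ERG/GATA1s against GATA1s 10, the interaction 1, GATA1s at E12.5 141 and ERG/GATA1s at E12.5 0. With trend and robust they were ERG/GATA1s against GATA1s 32, the interaction 6 and ERG/GATA1s at E12.5 3. With all probe sets they were ERG 25, ERG/GATA1s against GATA1s 4, the interaction 0 and GATA1s at E12.5 136. Without the 3 doubted arrays they were ERG 5, GATA1s 141, ERG/GATA1s 241, ERG/GATA1s against ERG 272, ERG/GATA1s against GATA1s 1, the interaction 0, GATA1s at E12.5 0, ERG/GATA1s at E12.5 0, ERG at E14.5 174, GATA1s at E14.5 72, ERG/GATA1s at E14.5 344, effects that differ between stages 6, carriers labelled male 75 and carriers labelled female 43. With a Y-linked level as covariate they were ERG 30, ERG/GATA1s 1030, ERG/GATA1s against ERG 722, ERG/GATA1s against GATA1s 7, the interaction 1, ERG/GATA1s at E12.5 0 and ERG/GATA1s at E14.5 755.

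The replicate number equals labelled sex, so the main fit already holds it as a block; with no replicate block the counts were 897 for ERG/GATA1s against ERG and 6 for ERG/GATA1s against GATA1s, and no other count moved by over 1.5 times. Arrays share only the number: deviations of same-numbered arrays correlated over 0.1 in 15 of 28 pairs of groups (-0.303 to 0.367). Of 131 list shifts called with the preset correlation, 0 passed with an estimated correlation and 38 with fry, which called 41 in all. Shared calls at an unadjusted p under 0.01 were 389 higher and 426 lower for GATA1s with and without ERG, 42 and 61 for ERG with and without GATA1s, 4 lower for ERG at both stages, 131 and 66 for GATA1s at both stages, 100 and 131 for ERG/GATA1s at both stages, and 423 and 388 for carriers by labelled sex.

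Leaving out 1 array gave 5 to 134 genes for ERG, 147 to 1055 for GATA1s, 788 to 4048 for ERG/GATA1s, 547 to 3954 for ERG/GATA1s against ERG, 0 to 44 for ERG/GATA1s against GATA1s and 0 to 20 for the interaction. At E12.5 it gave 0 to 9 for ERG, 0 to 461 for GATA1s and 0 to 3270 for ERG/GATA1s; at E14.5, 31 to 504, 42 to 956 and 507 to 1959. Stage gave 7665 to 10575, labelled sex and its interaction 0 to 0, effects that differ between stages 109 to 1055, carriers labelled male 155 to 1473, carriers labelled female 189 to 3355, and list shifts 109 to 145. The megakaryocyte and platelet list in ERG/GATA1s against GATA1s had adjusted p from 1.77e-07 to 0.531, and turned direction without the E14.5 GATA1s array labelled male (0.531). The megakaryocyte and platelet list in the GATA1s effect by sex had adjusted p from 0.001 to 0.997, and turned direction without either E12.5 WT array (0.874 for each) and without either E14.5 GATA1s array (0.997 for each).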
